A study of Caenorhabditis elegans with 2 samples.

How the data were processed

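Chromatin immunoprecipitation with an anti-GFP antibody was followed by sequencing in whole Caenorhabditis elegans of a line that stably carries CHE-1 fused to GFP and FLAG. CHE-1 is a zinc finger transcription factor known for specifying the ASE gustatory neurons. Both samples were late embryos taken 6 hours after synchronization by egg bleaching, and per the labels they are biological replicates 1 and 2 of 1 group. No second group, untagged strain or control library was analysed here, so no test between groups was made.

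The authors deposited lists of genomic regions. Per the descriptions deposited with the samples, 1 list was called for each replicate and 1 on both replicates together, each against a control and each including background regions meant as input for the irreproducible discovery rate procedure (IDR, which keeps regions ranked alike in replicates). An IDR-thresholded set was derived from them. The caller, its version, the aligner and the IDR threshold are not given in the sources used here. Each list other than the IDR set held 30000 regions. The deposited score of each region, in the signal column, is the authors' value relative to a control on a scale that is not stated, and it was used only to describe and rank regions within a list. The deposited q column is likewise a score of unstated scale and was not used for any test. In the 3 longer lists of build ce11 it ranked regions almost exactly as the signal column did. The summit is the position the authors' caller gave within each region. In build ce11 all 791 regions of the IDR set were the highest 791 regions of the list of both replicates together, and in build ce10 all 779 were. The files give no read counts, so the sequencing depth of each library is unknown. Exact binomial (Clopper-Pearson) 95% intervals cover counting error over peaks or genes only.

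Main results used build ce11, whose coordinates fitted within the chromosomes of the reference assembly WBcel235, with the Ensembl release 115 annotation. Symbols of mitochondrial genes that carry only an identifier there were taken from RefSeq genes of the same assembly that share at least 90% of both spans. The ce10 lists were used only where no annotation was needed. The text notes that accompany the lists were not used here. Coordinates are 1-based. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used.

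The 791 highest regions of each replicate were compared by an overlap of at least 1 bp. Location classes, in order of priority, were promoter (up to 1 kb upstream of a transcript start of a protein-coding gene), exon, intron and intergenic. Observed shares were set against 1000 circular shifts of the summits within chromosomes, whose smallest two-sided p is 0.002, and against the 29209 regions outside the IDR set by Fisher's exact test. The share on X was tested by an exact binomial test. The site GAARCC, the core described for CHE-1 in ASE neurons (R is A or G), was sought on either strand in the 101 bp around each summit and in a control window 500 bp away, by exact McNemar tests, with the reversed sequence CCRAAG as a composition control. All 2080 6-mers with reverse complements joined were tested in the same windows. A gene was assigned a peak when a summit lay between 2 kb upstream of its start and its end, and 21 gene lists were tested by Fisher's exact test against all other genes. Every test was two-sided, and p-values were adjusted by the Benjamini-Hochberg method within each family, with a threshold of 0.05. Permutation tests used 100000 resamples.

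Genes and peaks were named by a rule fixed, like the lists and the tests, before the data were examined. The rule takes the 20 IDR peaks with the highest score with the nearest protein-coding gene start, che-1 and unc-119, every ASE identity gene with a peak, the 4 genes with the strongest peak of each other list past the threshold, and the 5 6-mers with the smallest p. Comparisons with 9 classes of annotated non-coding genes, and the nuclear peaks and genes named there, were added after the data had been seen. In those, a peak belonged to a gene when its summit lay within 100 bp, and mitochondrial peaks and genes were left out.

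The 6-mer scan was tested on simulated data made of 791 pairs of random genomic windows. It recovered 10 of 10 6-mers planted in 10% of windows, 1 of 10 planted in 3%, and called 0 of 2080 with none planted. Both simulated window sets were drawn in the same way, whereas real summit windows held 48.5% G and C against 35.6% in control windows. The simulation therefore does not cover calls that arise from base composition. The gene list test recovered a 5-fold enrichment planted in 1 list of at least 60 genes in 99 of 100 runs, and called 4 of 2100 list tests with none planted. Genes outside the planted list were given a peak independently at the same rate, whatever their window length. Recovery in smaller lists, such as the ASE lists, was not simulated. Alternatives covered the build, a stricter set, merged peaks, each replicate alone, window sizes, the overlap rule, the assignment of peaks to genes and random lists matched on window length.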

Results

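Chromatin recovered with an anti-GFP antibody was mapped in whole late embryos that carry CHE-1 tagged with GFP. They were taken 6 hours after synchronization, in 2 biological replicates. The IDR set held 791 peaks, with a median width of 484 bp. The depth of the libraries is unknown, and peak scores are the authors' own values without a stated scale. The design allows 3 questions: where chromatin was recovered, how far the replicates shared those regions, and whether they lay at the genes and the DNA site known for CHE-1. No untagged strain was analysed here, so recovery that does not depend on CHE-1 cannot be told apart.

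The strongest IDR peaks lay on the mitochondrial genome and beside genes of small nucleolar RNAs (snoRNAs, which guide chemical modification of other RNAs). The 5 highest peaks were all mitochondrial, in the IDR set and in each replicate, as were 14 of the 20 highest. The 21 mitochondrial peaks formed 3 continuous regions covering 91.1% of the 13794 bp molecule. They thus spanned most of it, and whether their signal depends on the tagged protein was not tested. The highest, with a score of 3187, had its summit at position 12455 in ND5, a subunit of respiratory complex I. The next 4 had the starts of COX3 (score 2520, summit 5616), COX2 (2304, summit 9161), ND6 (2188, summit 194) and ATP6 (1982, summit 2260) nearest. The other 9 mitochondrial peaks among the 20 had scores from 995 to 1636, and were nearest to the starts of ND5, COX1, ND4, CYTB, COX2 and ATP6.

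The 6 nuclear peaks among the 20 highest all had an annotated snoRNA gene within 100 bp. The highest lay between genes on chromosome II at 11960559 to 11961113, with a score of 1683, at the snoRNA gene W03C9.9. Its nearest protein-coding start was that of W03C9.1. A peak on chromosome V at 12303372 to 12303891 (score 1489) lay in an intron of frm-7, at the snoRNA genes C51F7.4 and C51F7.3, with the start of F55C5.17 nearest. Others on chromosome V were in introns of pxn-1 (8500323 to 8500811, score 1337, at ZK994.7) and of cutl-18 (11314000 to 11314468, score 1203, at T03F7.8), and between genes near str-56 (15873726 to 15874211, score 1300, at T06C12.16). The remaining one was upstream of sre-23 on chromosome I (8259366 to 8259794, score 1274, at ZK265.10). All 6 ranked within the highest 20 regions of each replicate.

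The replicates shared most of their strongest regions. Of the 791 highest regions of replicate 1, 554 (70.0%, 95% interval 66.7 to 73.2%) overlapped one of the 791 highest of replicate 2, and 556 (70.3%) did so in the other direction. Circular shifts gave a mean of 3.44% and at most 4.55%. These shifts include the mitochondrial genome, where regions span most of the molecule and overlap after almost any shift. The overlap expected for nuclear regions alone is therefore lower and was not computed. Without mitochondrial regions the observed overlap was 69.1%. Shared regions were more often at a transfer RNA (tRNA) gene than regions high in 1 replicate only. The shares were 34.5% against 13.1% in replicate 1 (Fisher's exact test, p = 1.8e-10) and 34.5% against 6.38% in replicate 2 (Fisher's exact test, p = 4.9e-19), a comparison added after the data had been seen. In the list of both replicates the share at tRNA genes was 43% at nuclear ranks 1 to 100 and 4.10% at ranks 771 to 1600. Shared and unshared regions were not matched on rank, so this contrast is not separated from peak strength. Over the 790 IDR peaks found in both replicates, the Spearman correlation of scores was 0.794 (permutation p = 1e-05, the smallest the resamples can give). It is a correlation across peaks, which are not independent replicates, in a set selected for alike ranks, and 1 replicate region can stand for several IDR peaks. With each peak matched to the nearest summit it was 0.725, and without tRNA, snoRNA and mitochondrial peaks 0.608. The overlap was 57.2% over 2 times as many regions and 83.5% over 0.5 times as many.

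**Figure D1:**
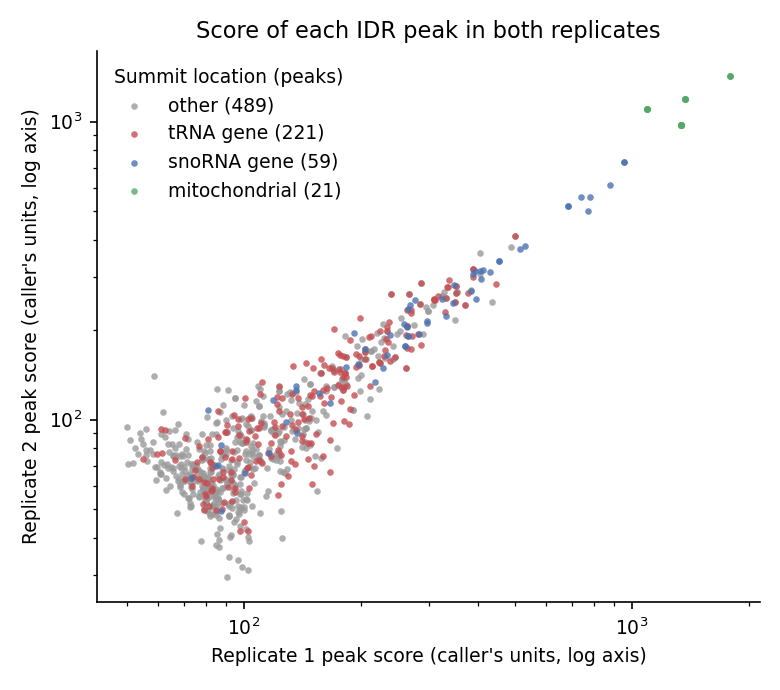
Score of each of 790 IDR peaks in replicate 1 (x, log axis) and replicate 2 (y, log axis), in the caller's own units, with colours for summits on the mitochondrial genome, within 100 bp of a nuclear tRNA or snoRNA gene, or elsewhere. Each score is that of the best overlapping region of the replicate, so 1 region can stand for several peaks. Mitochondrial peaks and then some snoRNA gene peaks have the highest scores in both replicates. Other snoRNA gene peaks are low, such as one at 73.0 in replicate 1 and 63.6 in replicate 2. The Spearman correlation over all points is 0.794.

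Many nuclear peaks lay at tRNA genes, in comparisons with 9 classes of non-coding genes that were added after the data had been seen. Of 770 nuclear peaks, 222 (28.8%) had their summit within 100 bp of a tRNA gene, against a mean of 1.45 peaks and at most 6 under circular shifts (permutation adjusted p = 0.0030). Of 612 nuclear tRNA genes, 226 carried a peak (36.9%, 95% interval 33.1 to 40.9%). snoRNA genes had 59 peaks (7.66%, shift mean 0.851), at 55 of 346 genes (15.9%, 95% interval 12.2 to 20.2%). Genes of small nuclear RNAs, the RNAs of the splicing machinery, had 10 peaks (shift mean 0.254) at 10 of 129 genes. Both classes had a permutation adjusted p of 0.0030, which is set by the smallest p that 1000 shifts allow.

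At snoRNA genes, 48 of 59 summits lay upstream of the gene and 6 downstream (exact binomial test, p = 3.3e-09), at a median of -43 bp from its start. At tRNA genes, 143 of 222 summits lay inside the gene, 61 upstream and 18 downstream (exact binomial test of upstream against downstream, p = 1.3e-06), at a median of 13 bp from its start. Summits thus lay inside tRNA genes more often than inside snoRNA genes, at 64.4% against 8.47% (Fisher's exact test, p = 1.5e-15). Of the regions outside the IDR set, 0.531% were at tRNA genes and 0.312% at snoRNA genes. The odds ratios of IDR peaks against them were 75.9 for tRNA genes (Fisher's exact test, adjusted p = 1.3e-259) and 26.6 for snoRNA genes (Fisher's exact test, adjusted p = 1.7e-53). Among the 50 strongest nuclear peaks, 22 were at snoRNA and 19 at tRNA genes. The class annotated as ncRNA had 237 peaks (shift mean 19.1, permutation adjusted p = 0.0030), of which 150 were also at a tRNA or snoRNA gene.

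Other non-coding classes held few peaks. Genes of piRNAs, small RNAs that silence transposons, had 3 peaks where shifts gave 14.8, and pseudogenes had 6 where shifts gave 24.7 (permutation adjusted p = 0.0030 for both). The share at piRNA genes did not differ from that of regions outside the IDR set (0.390% against 0.466%, Fisher's exact test, adjusted p = 1). MicroRNA genes had 3 peaks (shift mean 0.583, permutation adjusted p = 0.067), as did lincRNA genes (shift mean 2.06, adjusted p = 0.71) and antisense RNA genes (shift mean 0.899, adjusted p = 0.16), and none of these 3 classes passed the threshold.

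**Figure D2:**
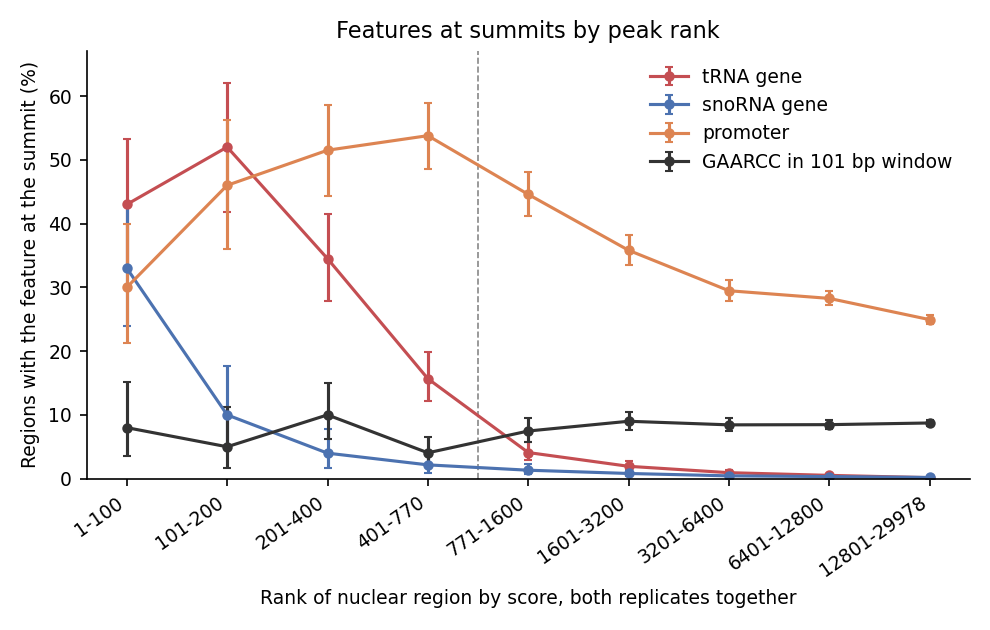
Percentage of nuclear regions whose summit lies at a tRNA gene, at a snoRNA gene, in a promoter, or with GAARCC in the window around the summit (y), by rank of the score in the list of both replicates (x), with exact binomial 95% intervals. The dashed line marks the end of the IDR set at nuclear rank 770. Ranks 1 to 100 hold 43% at tRNA and 33% at snoRNA genes, against 4.10% and 1.33% at ranks 771 to 1600, while GAARCC lies between 4.05% and 10% in every bin.

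Promoters of protein-coding genes held about every other peak. In the IDR set, 393 summits (49.7%, 95% interval 46.1 to 53.2%) were in a promoter, against 22.98% ± 1.54 (SD of 1000 shifts) by position alone. Exons held 4.93% against 24.5% and introns 21.1% against 27.8%, both lower (permutation adjusted p = 0.0027 for each of the 3 classes). Intergenic summits made up 24.3% against 24.7% (permutation adjusted p = 0.84). Compared with the regions outside the IDR set, of which 27.3% were in promoters, the odds ratio was 2.63 (Fisher's exact test, adjusted p = 4.7e-39). The lower share of introns was not past the threshold in the 395 strongest peaks (25.8% against 27.01%, permutation adjusted p = 0.84, range over all alternatives 0.0027 to 0.84). These shares include mitochondrial peaks. Promoters held 49.1% of the 770 nuclear peaks (shift mean 21.7%) and 59.1% of the 548 away from tRNA genes (shift mean 21.98%). Both sets were chosen after the data had been seen.

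Chromosome X carried 193 of the 770 nuclear peaks. That is 25.1% (95% interval 22.04 to 28.3%), where X makes up 17.7% of the nuclear genome (exact binomial test, p = 3.0e-07). Chromosome V held the smallest share, 11.7% of peaks on 20.9% of the sequence. X also holds 276 of the 612 nuclear tRNA genes (45.1%), and 96 of its peaks were at tRNA genes. Among the 548 nuclear peaks away from tRNA genes, 97 were on X (17.7%, 95% interval 14.6 to 21.2%; exact binomial test, p = 1), a comparison chosen after the data had been seen.

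**Figure D3:**
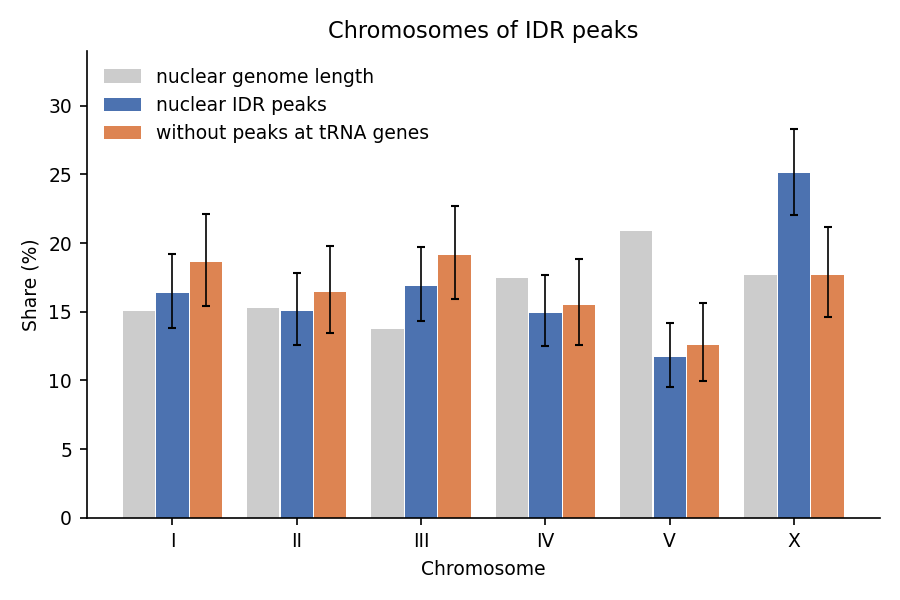
Share of each chromosome (x) in the nuclear genome length, in the 770 nuclear IDR peaks and in the 548 of them away from tRNA genes (y, percent), with exact binomial 95% intervals on the peak shares. X goes from 25.1% of all nuclear peaks to 17.7% of those away from tRNA genes, beside 17.7% of the genome.

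The CHE-1 site GAARCC was not enriched at IDR summits. It was present in 49 of 790 summit windows (6.20%, 95% interval 4.62 to 8.12%) and in 68 of the control windows (8.61%, 6.75 to 10.8%; exact McNemar test, p = 0.067). The composition control CCRAAG was found in 6.58% and 6.84% (exact McNemar test, p = 0.92). Summit windows were richer in G and C, at 48.5% against 35.6% in control windows. With control windows 1 kb away, GAARCC was less frequent at summits (6.21% against 10.0%, exact McNemar test, p = 0.0073, range over all alternatives 0.0073 to 0.89). No other alternative was past the threshold. Without mitochondrial peaks the shares were 6.23% against 6.62% (exact McNemar test, p = 0.84), and without replicate 2 they were 6.08% against 6.58% (p = 0.75).

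Of the 2080 6-mers, 847 differed between summit and control windows, 486 of them more frequent at summits and 361 less frequent. The control windows were not matched on base composition, with G and C at 35.6% against 48.5% in summit windows. These calls were therefore not separated from base composition. The 5 with the smallest p were AAAAAT (24.3% of summit against 50.5% of control windows, adjusted p = 2.3e-24), CTGAAA (4.68% against 22.4%, adjusted p = 8.0e-23), AAAATT (18.6% against 41.4%, adjusted p = 4.3e-20), TGAAAA (15.9% against 36.6%, adjusted p = 1.3e-18) and CGCACA (13.3% against 1.65%, adjusted p = 2.9e-17), all by exact McNemar tests. CGCACA was thus the leading 6-mer among those more frequent at summits. In the 548 peaks away from tRNA genes and the mitochondrial genome it was again first among those, at 17.7% against 1.28% (exact McNemar test, adjusted p = 1.2e-18). The 2 forms of the CHE-1 site, GAAACC (3.80% against 5.32%) and GAAGCC (2.53% against 3.54%), were not past the threshold (exact McNemar tests, adjusted p = 0.28 and 0.40).

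IDR peaks with GAARCC had a mean rank of 340 and those without it of 400, with rank 1 the strongest, a difference of -59.4 ranks (permutation p = 0.079). In the 548 peaks away from tRNA genes and the mitochondrial genome, a set chosen after the data had been seen, the difference was -83.9 ranks, with 31 peaks carrying the site (permutation p = 0.0037, range over all alternatives 0.0037 to 0.68). Without replicate 1 it was -12.9 ranks over 791 peaks (permutation p = 0.68), and with a wider window around the summit -23.3 (permutation p = 0.34).

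No gene of the ASE identity list carried an IDR peak. The list holds 32 genes known from these neurons, including receptor guanylyl cyclases (gcy genes), the cyclic nucleotide-gated channel genes tax-2 and tax-4, the regulators cog-1, die-1, lim-6 and lsy-6, and che-1 itself. With 0 of 32 genes (95% interval 0 to 10.9%) against 4.30% of the other 19954, the difference was not past the threshold (Fisher's exact test, adjusted p = 1). The 6 receptor guanylyl cyclases of ASER and the 4 of ASEL, the right and left cells of the pair, belong to the ASE identity list. Tested as lists of their own they thus add no separate evidence (Fisher's exact test, adjusted p = 1 for both). Their 95% intervals, 0 to 45.9% and 0 to 60.2%, are too wide to say much.

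Ribosomal protein genes and chemoreceptor genes were the lists past the threshold, 2 of 21. A peak lay at 15 of 78 ribosomal protein genes (19.2%, 95% interval 11.2 to 29.7%), against 4.23% of other genes (odds ratio 5.38, Fisher's exact test, adjusted p = 1.0e-05). The strongest were at rpl-3 (chromosome III, 3867480 to 3867660, -283 bp from the gene start, score 352), rpl-15 (IV, 654635 to 655118, -301 bp, score 259), rpl-11.1 (V, 3587600 to 3588083, -1778 bp, score 258) and rps-26 (I, 14759281 to 14759764, -407 bp, score 251). None of these 15 genes had a tRNA or snoRNA gene at a peak in its window. The list was not past the threshold when each peak went only to the nearest gene start (Fisher's exact test, adjusted p = 0.14, range over all alternatives 2.6e-07 to 0.14).

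Chemoreceptor genes, taken by symbol, had peaks less often than other genes, at 20 of 1364 (1.47%, 95% interval 0.898 to 2.26%) against 4.50% (odds ratio 0.316, Fisher's exact test, adjusted p = 3.9e-08). In fold over other genes this was 0.326, and 0.503 in the 395 strongest peaks, just past the threshold (Fisher's exact test, adjusted p = 0.048). The strongest peaks were upstream of sre-23 (score 1274, at a snoRNA gene), srt-11 (II, 14804343 to 14804941, score 641), srg-64 (X, 15741892 to 15742273, score 553, at a tRNA gene) and srd-43 (X, 13306934 to 13307220, score 532, at a tRNA gene). The symbol pattern also took some genes that are not chemoreceptor genes, such as src-1, a kinase gene, and srrt-1, which are among the 20.

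The other lists did not pass the threshold. Heat shock genes had peaks at 4 of 22 genes (18.2%, 95% interval 5.19 to 40.3%, Fisher's exact test, adjusted p = 0.093), namely hsp-60, hsp-1, hsp-90 and hsp-3, which code for protein folding factors. They had 2 of 22 without replicate 1 (Fisher's exact test, adjusted p = 0.81) and 5 of 22 without replicate 2, which was past the threshold (Fisher's exact test, adjusted p = 0.014). By the same Fisher's exact test, pan-neuronal genes had 4 of 27 (unc-104, unc-33, unc-119 and unc-44, adjusted p = 0.14), guanylyl cyclases of other cells 3 of 21 (gcy-33, gcy-35 and gcy-28, adjusted p = 0.21) and other neuron identity genes 4 of 41 (ets-5, cat-1, ast-1 and ttx-1, adjusted p = 0.29). Nuclear hormone receptor genes had 5 of 269 (Fisher's exact test, adjusted p = 0.20), collagen genes 8 of 156 (adjusted p = 0.96), cilia genes 2 of 47 (che-13 and daf-19, adjusted p = 1) and homeobox genes named ceh 0 of 63 (adjusted p = 0.30). Histone genes had 1 of 72 and other neuropeptide-like genes 1 of 71 (Fisher's exact test, adjusted p = 0.79 for both), and insulin-like genes 0 of 39 (adjusted p = 0.79). Muscle genes had 1 of 33, intestine genes 1 of 24, epidermis genes 1 of 29, germline genes 1 of 30 and FMRFamide-like peptide genes 1 of 31 (Fisher's exact test, adjusted p = 1 for each). Without replicate 1, pan-neuronal genes had 2 of 27 and other neuron identity genes 2 of 41, while guanylyl cyclases of other cells had 4 of 21, and 2 of 21 without replicate 2. Histone genes had 6 of 72 and muscle genes 3 of 33 without replicate 1, above other genes rather than below, and histone genes had 0 of 72 without replicate 2. The peaks at gcy-33, gcy-35, ets-5, cat-1 and unc-33 were at tRNA genes, and that at che-13 was at a snoRNA gene. Without tRNA and mitochondrial peaks the fold over other genes went from 3.34 to 1.42 for these guanylyl cyclases and from 2.28 to 1.45 for other neuron identity genes. The members named here for lists below the threshold were chosen after their values were seen. Among the 21 lists, 5 had an unadjusted p under 0.05.

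**Figure D4:**
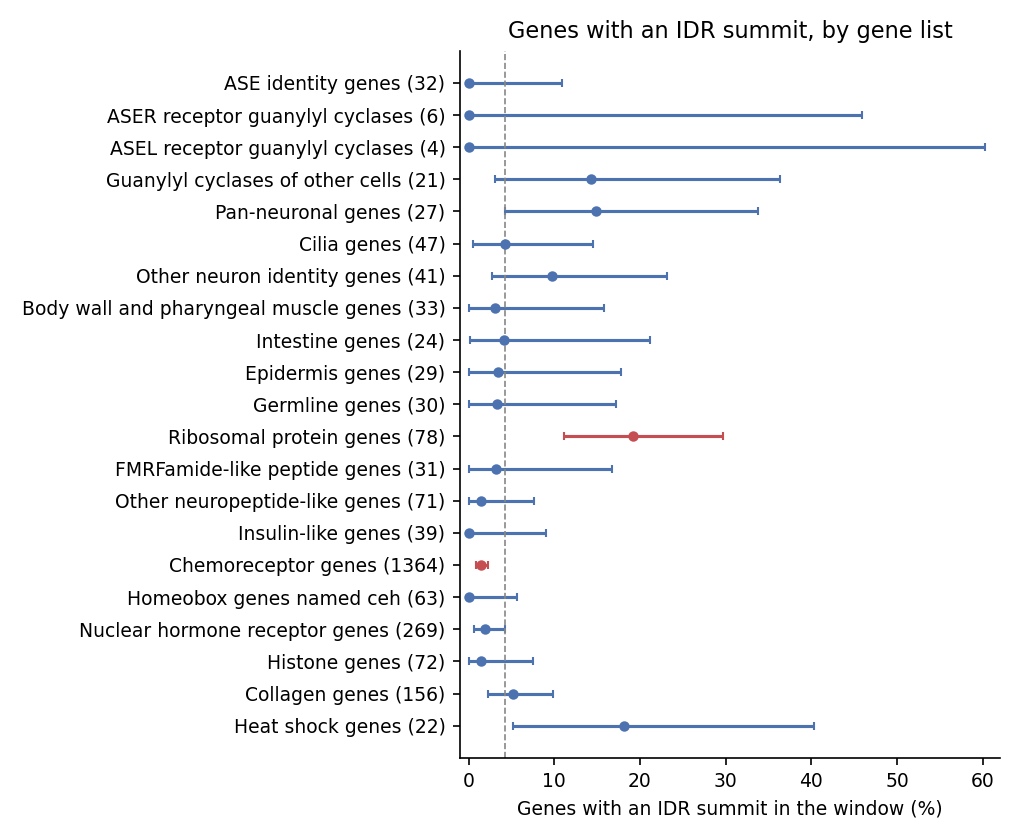
Percentage of genes with an IDR summit between 2 kb upstream of the start and the end of the gene (x) for each of 21 lists (y, with the number of annotated genes), with exact binomial 95% intervals. Red marks the lists with an adjusted p under 0.05, and the dashed line is the 4.29% of all 19986 genes. Ribosomal protein genes lie above it at 19.2% and chemoreceptor genes below it at 1.47%.

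The loci tied to the strain held no excess of peaks past the threshold. Few summits fall in such an interval under the shifts, so only a large excess could have been seen. Summits were counted, not signal. Within 20 kb of che-1 (chromosome I, 6517529 to 6520918), the gene of the tagged protein, there was 1 summit against a shift mean of 0.405 (permutation p = 0.60). It lay at nuo-2 (6531794 to 6532277), -11118 bp from the che-1 start, with a score of 171. Within 20 kb of unc-119 (chromosome III, 10902641 to 10908935), the gene mutated in the strain, there was 1 summit against 0.442 (permutation p = 0.70), inside the gene at 10906400 with a score of 137. Neither replicate alone had a summit in that interval among its 791 highest regions.

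GAARCC did not separate regions that the replicates shared from regions high in 1 of them. In replicate 1 it was found at 6.68% of 554 shared and 4.64% of 237 unshared regions (Fisher's exact test, p = 0.33), and in replicate 2 at 7.91% of 556 and 5.11% of the others (Fisher's exact test, p = 0.17).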

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

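The settings without tRNA, snoRNA or mitochondrial peaks were chosen after seeing the data. Of the comparisons set before the data were seen, 215 kept direction and side of the threshold, 21 turned direction, 6 moved, 3 became stronger and 2 weaker. Of the added ones 102 kept both, 3 turned, 3 moved, 5 became stronger and 2 weaker. The cause of the changes below was not tested, except that smaller sets hold fewer peaks by construction. The IDR set had 395 peaks in its stronger part and 489 without tRNA, snoRNA and mitochondrial peaks. Replicate overlap was 62.3% for summits within 100 bp, 64.2% for 0.5 of both regions, 83.5% over 0.5 times as many regions and 57.2% over 2 times as many. X held 17.7% of nuclear peaks without those at tRNA genes and 19.6% without those at snoRNA genes as well, and the 6-mers past the threshold then numbered 543 and 462. The rank difference of peaks with GAARCC was -83.9 and -66.4 in these sets, both past the threshold, but -52.7 to -12.9 without 1 replicate and -23.3 with a wider window, none of these past it. GAARCC was at 6.21% of summits with control windows 1 kb away, which was past the threshold. Intergenic summits were slightly above the shifts among the 395 (24.3%) and with a 500 bp promoter (31.98%), neither past the threshold. They were below the shifts without tRNA, snoRNA and mitochondrial peaks (20.7%, permutation adjusted p = 0.038).

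List directions that turned were all far from the threshold. In fold over other genes, the 395 strongest peaks gave intestine 1.98, germline 1.58 and FMRFamide-like peptide genes 1.53, and moved chemoreceptor genes to 0.503. Cilia genes were at 1.002 with merged peaks, 1.005 without mitochondrial peaks, 1.27 without tRNA and mitochondrial peaks, 1.38 with 2 kb upstream only and 1.21 by nearest start. Germline genes were at 1.09 without tRNA, snoRNA and mitochondrial peaks. Intestine genes were at 1.20 with 1 kb upstream. With 2 kb upstream only, other neuron identity genes were at 0.788, germline 1.08, FMRFamide-like 1.04 and collagen 0.828. Pan-neuronal genes then went from 3.46 to 1.20 and guanylyl cyclases of other cells from 3.34 to 1.54. Against the 4 and 3 genes with a peak in these 2 lists, lists matched on window length held means of 1.915 and 1.61 (permutation p = 0.24 and 0.42). Leaving out a replicate gave 1.78 to 3.49 for pan-neuronal genes and 1.17 to 1.72 for other neuron identity genes. Guanylyl cyclases of other cells were then at 2.24 to 4.598, muscle at 0.711 to 2.19, intestine at 0.977 to 1.002 and histone genes at 0 to 2.01. Cilia genes were at 0.511 to 0.998, epidermis at 0 to 0.809, ceh at 0 to 0.381 and insulin-like genes at 0 to 0.601. By nearest start, 1 list passed the threshold and ribosomal protein genes were at 2.57. Other neuron identity genes were then at 3.49, with 5 of 41 genes, not past the threshold (Fisher's exact test, adjusted p = 0.14). Heat shock genes passed it without replicate 2 (5.36 fold, Fisher's exact test, adjusted p = 0.014), without tRNA and mitochondrial peaks (5.43, 0.040), without snoRNA peaks as well (5.96, 0.029) and with 1 kb upstream (5.27, 0.045), but not without replicate 1 (2.19, 0.81).

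Summits near che-1 and near unc-119 numbered 0 among the 395 strongest peaks, and near unc-119 0 without either replicate. The GAARCC difference of shared regions in replicate 1 was -1.94 percentage points over 2 times as many regions. No paired analysis was possible because there is 1 group.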

Other observations

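The tests of the GC content of regions and of gene copies were set before their results were seen, and those on X, on ASE genes and on GAARCC were chosen after. ASE genes and chemoreceptor genes were sparse among all regions of the longer list. Of the 32 ASE identity genes, 9 (28.1%) had any of the 30000 regions of both replicates in their window, against 60.2% of other genes and 70.5% of lists matched on window length (permutation p = 2.0e-04, the smallest the random lists can give). The 9 were die-1, with the best rank of 1287, and cog-1 at rank 4866, gcy-19 at 7283, flp-25 at 9249, gcy-4 at 11172, gcy-22 at 11946, fozi-1 at 15687, ceh-36 at 18502 and gcy-14 at 28428. The window of che-1 had none. Chemoreceptor genes had 396 of 1364 (29.0%, 52.9% in matched lists, permutation p = 2.0e-04, again the smallest), so sparseness was not particular to ASE genes. Ribosomal protein genes had 71 of 78 (91.0%, 45.6% in matched lists), and others above matched lists included collagen genes (67.3%, 50.9% in matched lists, permutation p = 2.0e-04), epidermis genes (86.2%, 62.7%, p = 0.0080), pan-neuronal genes (96.3%, 79.0%, p = 0.020), ceh genes (77.8%, 63.8%, p = 0.022) and muscle genes (90.9%, 75.6%, p = 0.036). None of these p-values is adjusted, and they do not single out neuronal genes.

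The absence of the 32 ASE genes from the IDR set lies within chance, as matched lists held a mean of 1.94 genes with a peak (permutation p = 0.27), so it may need no cause. One hypothesis for the absence of ASE genes from the IDR set is weaker binding below the authors' threshold. It stays open: the 30000 regions include background, so the 28.1% against 70.5% does not measure it. For the lack of a GAARCC excess at IDR summits, the hypothesis weighed was that the site is enriched only among weaker regions. Over all 29998 regions with both windows GAARCC was at 8.56% of summits and 7.37% of control windows (exact McNemar test, p = 7.6e-08), but the composition control rose too, from 6.05% to 6.63% (p = 0.0032). With ratios of 1.16 and 1.10, and G and C at 40.8% of summit against 35.5% of control bases, an enrichment of the site cannot be told apart from base composition. The ASE pair is a small part of a whole embryo, and whether these neurons were too few to give peaks was not tested.

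The peaks at tRNA and snoRNA genes were weighed against GC content and reads shared between copies. GC content is argued against for both: other regions weighted to the same GC content were in the IDR set in 3.59% of cases where 58.9% of regions at tRNA genes were (95% interval 53.7 to 63.9%), and in 4.49% where 39.3% at snoRNA genes were (31.5 to 47.6%). Of the 304 snoRNA genes in which every 36-mer is unique, 50 carried a peak (16.4%, 69.0 times the shift mean). Peaks at snoRNA genes thus did not need copies of the gene sequence. Uniqueness was scored over the gene, whereas 48 of 59 summits lay upstream of it. Reads shared at the sequence under these summits were therefore not tested. For tRNA genes shared reads stay open: 0 of the 25 genes with every 36-mer unique, 0%, carried a peak, against 38.5% of the other 587 (Fisher's exact test, p = 8.5e-06). Of the 25, 9 had some region of the longer list, as did 374 of all 612 (61.1%), but that list includes background. Of 47 groups of identical tRNA sequences with a peak at some copy, 41 (87.2%) also held a copy without one. In these groups 194 of 444 genes carried a peak. Peaks are yes or no calls at a score cutoff, which copies of similar score can straddle. Scores of copies were not compared, so equal sharing among identical copies stays open. No untagged strain or other tagged factor was analysed here, so signal that does not depend on CHE-1 stays open too, and no biological explanation was tested.

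The excess of peaks on X may follow from where tRNA genes lie. Without peaks at tRNA genes X held 17.7% of nuclear peaks (95% interval 14.6 to 21.2%), which takes in its 17.7% of the nuclear genome. The explanation was found on the same data, and it leaves open what draws peaks to tRNA genes.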
